A study of Arabidopsis thaliana with 100 samples.

How the data were processed

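Roots of Arabidopsis thaliana accession Col-0 were profiled by RNA sequencing. Per the labels' protocols, seedlings were grown for 7 days on Johnson medium and then moved to the same medium with or without 1 µM flg22, a peptide of bacterial flagellin that plant cells recognise. The medium also held a live synthetic community of commensal bacteria (SynCom), the same community killed by heat, or no bacteria. The whole root system was harvested 1 or 12 days after transfer. Poly(A) RNA was made into non-stranded Illumina libraries, per the labels' protocols. The 100 libraries fell into 12 groups of 6 to 9 libraries, from 3 independent experiments, and groups, experiments and replicate numbers were taken from the sample labels.

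The deposited table held whole-number counts of reads per gene, with no normalization by the authors. Per the submitters' processing notes, bcl2fastq 2.20.0, FastQC, Trimmomatic, HISAT2, Subread and featureCounts were used with the TAIR10 genome. The versions of the last 5 tools, their settings and the annotation release are not given in the sources used here. The part of the table used here held 5088 complete gene rows from AT1G01010 to AT1G61800 on chromosome 1. One further line was incomplete, with 62 values for 100 libraries, and was left out. Genes beyond this range were not analysed here, and the genes held that were matched as protein coding made up 18.16% of the protein-coding genes in the reference. No column was left unused, 0 rows named no gene, and 493 genes had no count in any library.

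Gene names, products and coordinates came from the reference annotation of the TAIR10.1 assembly, in which 5006 of the gene identifiers were matched. Coordinates are 1-based and refer to that assembly. Because the libraries carried no strand, reads of a gene and of an overlapping antisense gene cannot be told apart. Transcripts were compared with BLAST+ 2.17.0, and 298 genes had a stretch of at least 100 bases at 95% identity or more in another gene. A further check of coordinates found 1388 genes that overlap another gene. Values of such genes are called uncertain where they are named.

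Library totals over the genes held ran from 254467 to 1333612 counts, with a median of 510177. These are partial sums and not the depth of the libraries. CPM values take the TMM-scaled total over the genes held as their base, not the whole library, and are given as mean ± SD over the libraries of a group. Scaling factors lay between 0.844 and 1.142 over the fits of day 1, day 12 and both days. Among the 373 pairs of libraries within groups, 0 were identical, and the chi-square per degree of freedom between pairs was at least 1.54, so no library was counted as a copy of another.

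The test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling, filterByExpr and robust dispersion. Each day was fitted on all 6 of its groups with experiment as a covariate, and a fit over both days served the day comparisons. In these fits libraries of the same experiment counted as separate replicates. The SE and adjusted p of edgeR therefore do not measure how an effect varies between experiments. Benjamini-Hochberg adjustment covered the 3122 genes tested at day 1, the 3320 at day 12 and the 3366 in the fit over both days. A gene was called at an adjusted p below 0.05. Differences between flg22 effects were tested as interaction contrasts. The median difference of the flg22 effect was taken over the genes that flg22 raised by a log2 fold change of at least 1 in the remaining kind of plants, so that the choice did not use either of the effects compared. It was tested with limma's fry, which asks whether the genes of a set move on balance one way, with Benjamini-Hochberg adjustment over the 5 median differences tested, or 10 with no fold floor.

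Named genes followed a rule. Among genes called in a comparison, with a mean log2 CPM of at least 1 over that day's libraries and a difference of the same sign in each of the 3 experiments, the 8 with the largest increase and the 8 with the largest decrease were taken. Comparisons of live with heat-killed SynCom, differences from the flg22 effect in heat-killed SynCom plants, and day comparisons took 4 in each direction. Members of gene lists were named by their p-value, up to 4 in each list. Lists covered defence, hormone, nutrient, cell wall and growth genes and markers of green shoot tissue. The groups, the tests, the rule, the lists and most alternatives were set before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, on log2 CPM with a prior count of 2, where at least 3 members were tested. Most list members lie outside the genes held, so protein families and annotated processes were added after the range of genes was seen and before any test was run. FLS2, the flg22 receptor, and FRK1, a flg22-response gene, lie outside that range and were not analysed here.

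The procedure was tested on simulated data with 200 changed genes, 50 at each size. Simulated libraries varied independently around an additive experiment term, with no group-by-experiment differences. The shares of recovered genes and false calls hold only for data of that kind. For the flg22 effect without bacteria at day 1, over 3122 genes, 46% of genes changed by 0.5 on the log2 scale were recovered, 92% of those changed by 1 and 100% of those changed by 2 or 3, and 1.2% of calls were false. The same shares at day 12, over 3320 genes, were 66%, 96%, 100% and 100%, with 2.2% false calls. For the difference between live SynCom and no bacteria at day 12 they were 48%, 88%, 100% and 100%, with 2.9% false calls. For day 12 against day 1, over 3366 genes, they were 56%, 92%, 100% and 100%, with 5.4% false calls. Overlaps between comparisons with the same control libraries were set beside 20 simulations of unchanged groups and 20 splits of the controls.

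Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, the replicate number as a block, no experiment term, counts summed per experiment, a fit on only the groups compared, each experiment left out in turn and, for the day comparisons, additive experiment terms. The contrasts within each experiment, a test of group-by-experiment terms, the fits without the no-bacteria mock libraries of experiment 3 at day 12 and those without the 3 libraries highest in photosynthesis transcripts were added after the data were seen.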

Results

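Gene counts were compared between Arabidopsis roots that had grown with or without the flagellin peptide flg22 (1 µM) and with a live SynCom, a heat-killed SynCom or no bacteria. Roots harvested at day 1 formed 6 groups. There were 8 mock and 9 flg22 libraries without bacteria, 9 and 6 with heat-killed SynCom, and 7 and 9 with live SynCom. At day 12 there were 7 mock and 9 flg22 libraries without bacteria and 9 in each of the other groups. Each group drew on 3 experiments. Totals over the 5088 genes held, which are only a part of each library, ran from 254467 to 1333612 counts with a median of 510177.

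Experiment had a measurable effect on many genes, above all at day 12. In tests added after the data were seen, an experiment term was called for 167 of 3122 genes at day 1 and 2080 of 3320 at day 12, and a group-by-experiment term for 5 and 435 genes. Markers of green shoot tissue were high in 3 live SynCom libraries of experiment 2. Over 6 photosynthesis genes, the summed level was 13851.3 CPM in mock replicate 2 at day 1 (5.86 times its group median), 12086.3 CPM in flg22 replicate 2 at day 1 (6.29 times) and 7033 CPM in mock replicate 3 at day 12 (4.62 times).

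Values of some named genes are uncertain because their reads can be shared. AT1G05250, IGMT2, AT1G21400, CAB2 and AT1G38131 have a near-identical stretch in another gene. UGT75B1, AT1G26250, KCS2, MYC2, AT1G31760, ATAF1, AT1G33600, AT1G06710, BCAT-2, AT1G10640, THA1 and AT1G51620 overlap an antisense gene by over 100 bases, and AT1G49030 and PGSIP4 overlap a gene on the same strand. GRI, RBOHB, AT1G30870, AT1G09750, EXPA7 and GolS4 have shorter overlaps.

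The question of how roots respond to flg22 alone was addressed by flg22 against mock without bacteria. At day 1 (9 and 8 libraries) the phi-class glutathione S-transferases GSTF6 (AT1G02930, chromosome 1, 661088 to 662475) and GSTF7 (AT1G02920, 658578 to 659980), which conjugate glutathione to reactive compounds, showed the largest increases. GSTF6 rose from 95 ± 49 CPM (SD, n = 8) to 1050 ± 216 CPM (SD, n = 9), a log2 fold change of 3.43 ± 0.39 (SE, edgeR adjusted p = 7.3e-08), and GSTF7 rose by 2.70 ± 0.36 (edgeR adjusted p = 2.76e-06). The root-hair cell wall gene PRP1 (AT1G54970, 20504901 to 20506504) rose by 2.34 ± 0.37 and the kinase gene AT1G51620 by 1.92 ± 0.35. Smaller increases were seen for ORA59, an ethylene and jasmonate response factor (1.49 ± 0.37), AT1G49030 (1.47), AT1G13480 (1.36) and the protein phosphatase 2C gene AT1G07160 (1.2). The aspartyl protease gene AT1G09750 (3157501 to 3159148) went from 129 ± 20.8 CPM (SD, n = 8) to 11.2 ± 10.4 CPM (SD, n = 9) and thus fell by 3.51 on the log2 scale (SE 0.37, edgeR adjusted p = 8.06e-09). Decreases were also called for the transporter gene AT1G52190 (-2.11), the extensin-like gene ELP (-1.67), the pectin acetylesterase gene AT1G57590 (-1.63), AT1G06120 (-1.36), AT1G22330 (-1.34), PKS2 (-1.26) and AT1G38131 (-1.17).

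Of the early flg22 markers tested in the same comparison, MYB51, an activator of indole glucosinolate synthesis, rose by 0.98 ± 0.22 (edgeR adjusted p = 0.00522). Among 5 indole glucosinolate genes, a class of defence compounds, 1 was higher over all genes tested and 3 were higher when adjusted over the list alone (camera adjusted p = 0.00207), and adjusted p = 0.0844 with an estimated correlation. Among 3 root hair genes 1 was higher, the expansin gene EXPA7 at 0.69, and 2 were higher when adjusted over the list alone (camera adjusted p = 0.00443), and adjusted p = 0.131 with an estimated correlation. The 6 photosynthesis markers held 0 called genes by edgeR (camera adjusted p = 0.199). In all, 71 of 3122 genes were called, 39 higher and 32 lower, of which 13 and 8 changed at least 2-fold. Each of the 71 had the same sign in each experiment. Here and in the comparisons below, such sign counts cover genes called from the same libraries. Agreement is therefore favoured by construction and is not an independent replication. Within single experiments 22, 9 and 11 genes were called, and the pooled count was 30 without experiment 1, 37 without experiment 3 and 25 with counts summed per experiment.

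With heat-killed SynCom at day 1 (6 flg22 and 9 mock libraries), GSTF6 rose by 3.4 ± 0.38 (edgeR adjusted p = 6.97e-08), GSTF7 by 2.86 ± 0.37, PRP1 by 1.74 and the zinc finger gene SOM by 1.73. AT1G13480 (1.48), AT1G07160 (1.36), AT1G49030 (1.32) and AT1G51620 (1.31) were also higher. AT1G09750 fell by 4.09 (SE 0.47, edgeR adjusted p = 6.97e-08), AT1G57590 by 3.16, AT1G06120 by 2.02 and ELP by 1.95, with AT1G05660 (-1.44), AT1G22330 (-1.36), PKS2 (-1.33) and AT1G06710 (-0.97) lower as well. MYB51 rose by 1.04 ± 0.24 (edgeR adjusted p = 0.00618), and 2 of 3 root hair genes were higher, over all genes and adjusted over the list alone alike (camera adjusted p = 0.077). Over 3122 genes, 37 were higher and 31 lower, of which 13 and 7 changed at least 2-fold, and all 68 had the same sign in each experiment. Within experiments 10, 9 and 9 genes were called. The pooled count was 21, 33 and 26 without experiments 1, 2 and 3, and 33 with counts summed per experiment.

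Live SynCom plants at day 1 (9 flg22 and 7 mock libraries) also showed higher GSTF6 with flg22 (log2 fold change 3.52 ± 0.39, edgeR adjusted p = 4.13e-08), at 1320 ± 884 CPM (SD, n = 9) against 109 ± 51.1 CPM (SD, n = 7). GSTF7 rose by 3.0 ± 0.37, the inositol phosphatase gene 5PTASE11 by 1.72 ± 0.26 and the thionin-like gene AT1G25275 by 1.36 ± 0.17. AT1G49030 (1.76), AT1G13480 (1.69), AT1G51620 (1.58), AT1G07160, MYB51 (1.13, edgeR adjusted p = 0.000398) and ORA59 (1.31) were higher too. AT1G09750 fell by 1.94 (SE 0.29, edgeR adjusted p = 1.48e-05), from 171 ± 21.2 CPM (SD, n = 7) to 46.6 ± 49.5 CPM (SD, n = 9). The sizes differed by experiment, with log2 differences of -2.37, -0.87 and -4.13 for AT1G09750 and 4.25, 1.87 and 3.41 for GSTF6 in experiments 1, 2 and 3. In the 3 flg22 libraries of experiment 2 AT1G09750 stood at 53.6 to 134 CPM and GSTF6 at 185 to 297 CPM, against 3.17 to 38.9 CPM and 1329 to 2614 CPM in the other experiments. Without experiment 2 the fold change of AT1G09750 was -3.20, and without experiment 1 it was -1.78 and not called (edgeR adjusted p = 0.0574). AT1G57590 (-1.61), AT1G06120 (-1.46), AT1G22330 (-1.02), AT1G19900 (-0.98), the glutathione S-transferase gene GSTU14 (-0.93), AT1G14185 (-0.92) and AT1G12080 (-0.80) were lower. Of 3122 genes 37 were higher and 20 lower, 16 and 4 of them at least 2-fold. Without the libraries highest in photosynthesis transcripts, 28 were higher and 11 lower, and AT1G22330 (-0.85) and AT1G14185 (-0.80) were not called. The count rested on experiment and design, with 33, 174 and 58 genes called within experiments 1, 2 and 3, 17 without experiment 1, 230 without experiment 3, 34 with counts summed per experiment and 31 in a fit of only these groups.

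The 3 flg22 effects at day 1 were then compared with each other. Over 13 genes that flg22 raised at least 2-fold with heat-killed SynCom, including GSTF6 and GSTF7, the effect with live SynCom differed from that without bacteria by a median of 0.21 on the log2 scale (fry adjusted p = 0.923). The median was 0.14 for live minus heat-killed over 13 genes (fry adjusted p = 0.923) and -0.03 for heat-killed minus no bacteria over 16 genes (fry adjusted p = 0.923). The sets that flg22 lowered at least 2-fold held fewer than 10 genes and were not tested. The median was 0.82 for live minus heat-killed over 8 genes, 0 of them below 0, with flg22 effects of -0.94 and -1.66, 0.32 for live minus no bacteria over 7 genes and -0.62 for heat-killed minus no bacteria over 4 genes. With no fold floor, live minus heat-killed was 0.22 over 32 lowered genes, 4 of them below 0, which passed by camera (adjusted p = 3.78e-06, and adjusted p = 0.0406 with an estimated correlation) and not by fry (adjusted p = 0.111). In the gene-by-gene interaction tests edgeR called 0 of 3122 genes for live against none, 0 for heat-killed against none and 0 for live against heat-killed, with 93, 66 and 70 genes at an unadjusted p under 0.05 and 0 calls by DESeq2 in each. Those are smaller shares than the 0.05 that p-values without any effect would give on average. The simulated data held no interaction at day 1, and the common dispersion was 0.0287 at day 1 against 0.014 at day 12. The 0 calls thus do not show that the effects were equal. Leaving out experiment 2, or the libraries highest in photosynthesis transcripts, gave 1 call in live against heat-killed, a lower effect on GSTU14, which is named after its values were seen. The root hair list, with 0 of 3 genes called, gave camera adjusted p = 0.00661 for a lower effect with live SynCom than without bacteria, and adjusted p = 0.23 with an estimated correlation.

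Bacteria alone were assessed in mock plants. After 1 day with live SynCom (7 against 8 libraries), AT1G33840, which encodes a LURP-one-like protein, rose from 3.12 ± 3.53 CPM (SD, n = 8) to 37.5 ± 13.1 CPM (SD, n = 7), a log2 fold change of 3.41 ± 0.42 (edgeR adjusted p = 3.19e-08). AT1G44030 rose by 2.19, PRP1 by 2.02 ± 0.38, PGSIP4 by 1.89, the sulfotransferase gene ST4B by 1.86 ± 0.28, AT1G01660 by 1.85, AT1G14960 by 1.77 and the high-affinity nitrate transporter gene NRT2:1 by 1.46 ± 0.37. The tau-class glutathione S-transferase gene GSTU24 (AT1G17170, 5869543 to 5870883), whose product conjugates glutathione to foreign compounds, went from 1500 ± 177 CPM (SD, n = 8) to 553 ± 155 CPM (SD, n = 7) and fell by 1.48 (SE 0.13, edgeR adjusted p = 6e-13), and the glucosyltransferase gene UGT75B1 fell by 1.67. The beta-glucosidase gene BGLU11 (AT1G02850, 630374 to 633420) went from 780 ± 125 CPM (SD, n = 8) to 296 ± 93.1 CPM (SD, n = 7, edgeR adjusted p = 2.07e-09). The remaining named decreases were 5PTASE11 (-1.64), the oxidoreductase genes AT1G60750 (-1.57) and AT1G60730, THA1 (-1.39) and AT1G60740 (-1.34).

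In the same comparison 2 of 3 root hair genes, EXPA7 (0.78 ± 0.16) and LRX1 (0.86), were higher, over all genes and adjusted over the list alone alike (camera adjusted p = 0.0114), and adjusted p = 0.27 with an estimated correlation. Among auxin genes SHY2, a repressor of auxin response, rose by 0.73 and AT1G14130, which encodes an auxin oxidase, fell by 0.75. PHI-1, an early flg22 marker, fell by 0.98. Of 32 leucine-rich repeat receptor kinase genes 4 were higher (camera adjusted p = 0.00298), among them AT1G07550 (1.21) and AT1G29740 (1.28), with adjusted p = 0.42 with an estimated correlation. In total 65 genes were higher and 90 lower of 3122, with 23 and 16 at least 2-fold, and 155, 155 and 145 of the 155 had the same sign in experiments 1, 2 and 3. Within experiments 28, 137 and 2 genes were called, and the pooled count was 61 without experiment 1, 33 without experiment 2, 84 with counts summed per experiment and 100 without the libraries highest in photosynthesis transcripts, where THA1 was not called (-1.31, edgeR adjusted p = 0.0787).

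Heat-killed SynCom at day 1 gave 0 calls of 3122 genes by edgeR and 0 by DESeq2. An unadjusted p under 0.05 was found for 118 genes, a smaller share than the 0.05 that p-values without any effect would give on average. Live against heat-killed SynCom (7 and 9 mock libraries) gave 45 higher and 92 lower genes, 16 and 13 of them at least 2-fold. AT1G33840 was higher by 3.04, AT1G44030 by 1.68, the extensin-like gene AT1G26250 by 1.57 and AT1G01660 by 1.45. GSTU24 was lower by 1.46 (SE 0.12, edgeR adjusted p = 4.97e-13), UGT75B1 by 1.61 (SE 0.16), 5PTASE11 by 1.74 and AT1G60750 by 1.52. In the Casparian strip and suberin list, genes for the root's apoplastic barriers, 2 of 3 were lower, KCS2 (-0.66) and LACS2 (-0.53), and 3 when adjusted over the list alone (camera adjusted p = 0.00411), and adjusted p = 0.0984 with an estimated correlation. Of 14 NAC transcription factor genes 4 were lower, ATAF1 (-0.70), NAC003 (-0.95), NAC010 (-0.73) and NAC001 (-0.43), with camera adjusted p = 0.0115, and adjusted p = 0.0465 with an estimated correlation. Within experiments 32, 85 and 8 genes were called, with 137, 136 and 129 of the 137 pooled calls in the same direction. The count was 62 without experiment 1, 55 without experiment 2 and 75 with counts summed per experiment.

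At day 12 without bacteria (9 flg22 and 7 mock libraries), PRP1 rose from 16.7 ± 11.8 CPM (SD, n = 7) to 264 ± 111 CPM (SD, n = 9), a log2 fold change of 4.11 ± 0.44 (edgeR adjusted p = 2e-09). The peroxidase genes AT1G34510 (12615690 to 12617032) and AT1G14550 rose by 3.5 ± 0.57 and 2.21 ± 0.25, GRI (AT1G53130, 19794723 to 19795544), known from cell death signalling, by 2.01 ± 0.34, and the late embryogenesis abundant-like gene AT1G54890 by 1.98 ± 0.13 (edgeR adjusted p = 3.23e-16). AT1G01453 (2.17), AT1G50050, of the family that holds pathogenesis-related protein 1 (1.96), and the methyl esterase gene MES13 (1.79) were higher as well. FMO1 (AT1G19250, 6650476 to 6653195), whose product makes N-hydroxypipecolic acid in systemic resistance, went from 45.0 ± 22.4 CPM (SD, n = 7) to 1.76 ± 1.92 CPM (SD, n = 9) and fell by 4.49 (SE 0.46, edgeR adjusted p = 1.53e-10). AT1G26240, an extensin-like gene (-2.92), the berberine bridge enzyme gene AT1G26390 (-2.05), ARI12 (-1.99), AT1G58320 (-1.55), AT1G53610 (-1.44), the lipase gene AT1G29660 (-1.39) and AT1G26250 (-1.31) were lower.

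Of 8 class III peroxidase genes tested in that comparison 6 were higher, among them AT1G14550, AT1G34510, PER4 (1.40 ± 0.23) and AT1G30870 (1.09 ± 0.21), with camera adjusted p = 9.03e-10, and adjusted p = 0.00152 with an estimated correlation. All 3 root hair genes were higher, LRX1 (1.12 ± 0.23), EXPA7 (0.66) and the transcription factor gene RSL4 (0.65), over all genes and adjusted over the list alone alike (camera adjusted p = 0.000104), and adjusted p = 0.0359 with an estimated correlation. Of 5 indole glucosinolate genes 2 were higher, MYB51 (0.81 ± 0.20) and the transporter gene PEN3 (0.36 ± 0.10), and 4 passed when adjusted over the list alone, of which 3 were higher (camera adjusted p = 0.284). SD1-29, the receptor kinase LORE that recognises bacterial lipids, was the called member of 4 pattern receptor genes, with an increase of 1.00 ± 0.14 (edgeR adjusted p = 6.5e-07). Of 3320 genes 111 were higher and 45 lower, 42 and 9 at least 2-fold, and 154, 152 and 155 of the 156 had the same sign in experiments 1, 2 and 3. Within experiments 94, 96 and 383 genes were called, and the pooled count was 71 with no experiment term and 62 with counts summed per experiment. Without the no-bacteria mock libraries of experiment 3, AT1G26240 (-1.19), AT1G58320 (-0.73), AT1G53610 (-1.07), the peroxidase gene AT1G05250 (0.79, edgeR adjusted p = 0.0583, against 0.92 with all libraries), EXPA7 (0.54, edgeR adjusted p = 0.099) and RSL4 (0.53, edgeR adjusted p = 0.0895) were not called. In that fit AT1G26390 was still called at a smaller change of -1.31 (edgeR adjusted p = 0.0321) and MYB51 at a larger one of 1.31 (edgeR adjusted p = 1.66e-06).

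With heat-killed SynCom at day 12 (9 and 9 libraries), GSTF6 rose from 45.2 ± 25.7 to 507 ± 133 CPM (SD, n = 9 each), a log2 fold change of 3.48 ± 0.37 (edgeR adjusted p = 1.21e-09). PRP1 rose by 3.03 ± 0.38, GRI by 2.64 ± 0.32, the leucine-rich repeat gene AT1G33600 by 2.54 ± 0.24, AT1G34510 by 2.52, AT1G14550 by 2.46 ± 0.24, the indole glucosinolate methyltransferase gene IGMT4 by 2.17 and GSTF7 by 2.01. FMO1 fell by 3.07 (SE 0.44, edgeR adjusted p = 4.49e-07), and AT1G44030 (-1.94), ARI12 (-1.58), AT1G11740 (-1.17), AT1G04150 (-1.14), COBL6 (-1.05), AT1G23160 (-0.94) and GSTU14 (-0.92) were lower. ORA59 fell by 1.39. Of 5 indole glucosinolate genes 3 were higher, PEN3 (0.63 ± 0.10), IGMT2 (1.49 ± 0.28) and MYB51 (0.94 ± 0.19), over all genes and adjusted over the list alone alike (camera adjusted p = 0.000294), and adjusted p = 0.0362 with an estimated correlation. SD1-29 rose by 0.92 ± 0.13, and 2 of 3 root hair genes, EXPA7 (0.61) and LRX1 (0.90), were higher (camera adjusted p = 0.00697), and adjusted p = 0.155 with an estimated correlation.

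Of 8 class III peroxidase genes, 5 were higher with heat-killed SynCom and flg22, among them PER4 at 1.81 ± 0.22 (camera adjusted p = 7.82e-08), and adjusted p = 0.0067 with an estimated correlation. Among 34 leucine-rich repeat receptor kinase genes 9 were higher, led by AT1G29740 (1.63), AT1G51850 (1.01), AT1G29730 (0.93) and IOS1 (0.90), with camera adjusted p = 0.00197, and adjusted p = 0.11 with an estimated correlation. Of 12 mannose-binding lectin and jacalin genes 4 were higher (camera adjusted p = 0.0118), and adjusted p = 0.0315 with an estimated correlation. Genes annotated to defense response included 6 higher of 35 (camera adjusted p = 0.000545), and adjusted p = 0.0353 with an estimated correlation. Over 3320 genes, 156 were higher and 72 lower, 37 and 7 at least 2-fold, and 225, 224 and 228 of the 228 had the same sign in experiments 1, 2 and 3, within which 203, 81 and 172 genes were called. The count was 145 without experiment 3, 114 with no experiment term and 74 with counts summed per experiment.

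With live SynCom at day 12 (9 and 9 libraries) flg22 changed 1 gene, the glutaredoxin gene GRXS13 (AT1G03850), which rose by 1.04 ± 0.21 (edgeR adjusted p = 0.0306) and had the same sign in each experiment. GSTF6 was at 157 ± 60.2 CPM with flg22 and 144 ± 67.3 CPM in mock, PRP1 at 216 ± 141 and 273 ± 190 CPM, FMO1 at 7.87 ± 2.31 and 7.11 ± 4.98 CPM, and AT1G34510 at 53.0 ± 37.8 and 60.6 ± 48.6 CPM (SD, n = 9 each). Of 3320 genes 361 had an unadjusted p under 0.05, and DESeq2 called 12. Without the libraries highest in photosynthesis transcripts 2 genes were called, GRXS13 and AT1G20880, the latter named after its values were seen. The count depended on the experiments, with 258, 0 and 7 genes called within experiments 1, 2 and 3, and 0, 27 and 52 without each in turn; it was 15 in a fit of only these groups, 0 with no experiment term and 0 with counts summed per experiment.

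**Figure D1:**
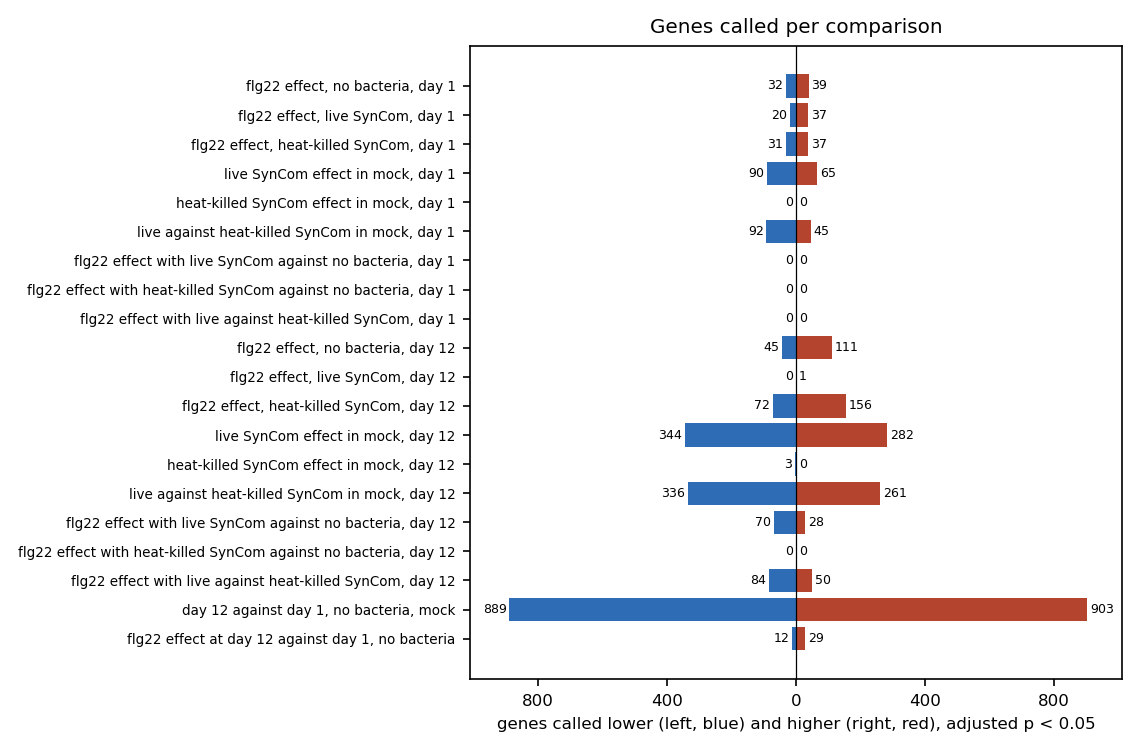
Bars give the number of genes called lower (left) and higher (right) by edgeR in each comparison, out of 3122 genes at day 1, 3320 at day 12 and 3366 for the comparisons of days. With flg22 at day 12, 111 genes were higher and 45 lower without bacteria, 156 and 72 with heat-killed SynCom, and 1 and 0 with live SynCom.

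The difference between flg22 effects at day 12 was tested directly. Against plants without bacteria, the effect with live SynCom was lower for PRP1 by 4.42 (SE 0.54, edgeR adjusted p = 3.04e-07), AT1G34510 by 3.67 (SE 0.66), and GRI by 3.32 (SE 0.54). Differences of -2.97 for the sulfate transporter gene SULTR1;3, -2.93 for CAB2 (SE 0.84, edgeR adjusted p = 0.0403), -2.45 for MES13, -2.35 for AT1G07160 and -2.26 for AT1G01453 were also called. The effect was higher for FMO1 by 4.55 ± 0.76 (edgeR adjusted p = 6.08e-05), and also for AT1G26240 (2.89), AT1G53610 (2.33), ARI12 (1.76), AT1G26250 (1.73), AT1G29660 (1.57), the galactinol synthase gene GolS4 (1.34) and the NADPH oxidase gene RBOHB (0.92). FMO1 averaged 45.0 CPM in mock and 1.76 CPM with flg22 without bacteria, and 7.11 and 7.87 CPM with live SynCom. Part of its difference thus lies in the lower mock level with live SynCom. Of 8 class III peroxidase genes 3 had a lower effect, and 5 when adjusted over the list alone (camera adjusted p = 4.43e-06), and adjusted p = 0.028 with an estimated correlation. SD1-29 (-1.11, edgeR adjusted p = 0.000295), PHI-1 (-1.31) and LRX1 (-1.05, edgeR adjusted p = 0.0487) were lower, the last as 1 of 3 root hair genes called and 3 when adjusted over the list alone (camera adjusted p = 0.00886), and adjusted p = 0.251 with an estimated correlation. CAB2 was the called member of 6 photosynthesis markers, 2 of which passed when adjusted over the list alone (camera adjusted p = 0.0327), and adjusted p = 0.692 with an estimated correlation. Its level was 201 ± 432 CPM in the 9 live mock libraries, and without the library of that group highest in photosynthesis transcripts its difference was -1.59 (edgeR adjusted p = 0.225) and it was not called, as also without the no-bacteria mock libraries of experiment 3, where its difference was no smaller (-2.96, edgeR adjusted p = 0.0822).

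In that comparison 28 genes had a higher and 70 a lower effect with live SynCom, 7 and 41 by at least 2-fold. The 98 calls had the same sign 98, 97 and 98 times in experiments 1, 2 and 3, within which 90, 8 and 340 were called. Without the libraries highest in photosynthesis transcripts 92 genes were called, and without the no-bacteria mock libraries of experiment 3, 61 (8 higher and 53 lower). In the latter fit AT1G26240 (1.2), AT1G53610 (1.96), ARI12 (1.40), AT1G29660 (1.61, no smaller than with all libraries), PHI-1 (-1.0, edgeR adjusted p = 0.179) and LRX1 (-0.85, edgeR adjusted p = 0.226) were not called. The count was 46 without experiment 3, 30 with no experiment term and 11 with counts summed per experiment.

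Against heat-killed SynCom the flg22 effect with live SynCom was lower for GRI by 3.95 (SE 0.54, edgeR adjusted p = 7.75e-07), with differences of -3.34 (SE 0.49) for PRP1, -3.25 (SE 0.53, edgeR adjusted p = 6.72e-05) for GSTF6 and -2.98 for AT1G33600. It was higher for FMO1 by 3.13 ± 0.71 (edgeR adjusted p = 0.00393), AT1G44030 by 2.12, AT1G31760 by 1.29 and GRXS13 by 1.27. In mock plants FMO1 averaged 7.11 CPM with live and 21.2 CPM with heat-killed SynCom, so part of its difference again lies in the mock level. Of 8 class III peroxidase genes 3 had a lower effect, AT1G14550 (-2.16), PER4 (-1.54) and AT1G34510 (-2.69), with camera adjusted p = 7.63e-05, and adjusted p = 0.0271 with an estimated correlation. SD1-29 (-1.03) and PEN3 (-0.54 ± 0.14) were lower, PEN3 being 1 of 5 indole glucosinolate genes called and 3 passing when adjusted over the list alone (camera adjusted p = 0.0819). In total 50 effects were higher and 84 lower, 13 and 37 by at least 2-fold, and 133, 122 and 132 of the 134 kept their sign in experiments 1, 2 and 3, within which 430, 17 and 81 were called. The count was 44 without experiment 1, 209 without experiment 2, 42 with no experiment term and 20 with counts summed per experiment. FMO1 was no longer called without experiment 1 (3.17, edgeR adjusted p = 0.0543) or without experiment 2 (2.58, edgeR adjusted p = 0.0534). For heat-killed SynCom against no bacteria edgeR called 0 of 3320 genes, with 150 at an unadjusted p under 0.05, a share that is itself below 0.05. DESeq2 called 1 gene, GSTF6, whose flg22 effect without bacteria by edgeR was 1.25 with the 2 no-bacteria mock libraries of experiment 3 and 2.5 without them, against 3.48 with heat-killed SynCom, and DESeq2 was not run without them. Without experiment 2 edgeR called 6 genes. The cell cycle and indole glucosinolate lists held 0 called genes and gave camera adjusted p = 0.0193 and 0.0219, and adjusted p = 0.264 for both with an estimated correlation.

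Genes raised by flg22 were then compared as sets. The 37 genes that flg22 raised at least 2-fold with heat-killed SynCom, PRP1, GRI, AT1G34510 and IGMT4 among them, had a median flg22 effect of 1.27 without bacteria and 0.06 with live SynCom. Their median difference was -1.18, with quartiles of -1.90 and -0.75 and 35 of 37 genes below 0 (fry adjusted p = 5.95e-13). The 42 genes that flg22 raised at least 2-fold without bacteria had a median effect of 1.15 with heat-killed and -0.04 with live SynCom, a median difference of -1.31 with 41 genes below 0 (fry adjusted p = 5.95e-13). Within experiments 1, 2 and 3 the medians of the latter were -1.09, -0.92 and -1.63. The fry test, like edgeR and camera, counted each library as a replicate, so its p-values do not measure the spread between experiments. The median differences were not run with counts summed per experiment. The corresponding sets of genes that flg22 lowered at least 2-fold held fewer than 10 genes and were not tested. Larger sets of lowered genes, taken with no fold floor, were tested at day 12, and their values are not given here.

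**Figure D2:**
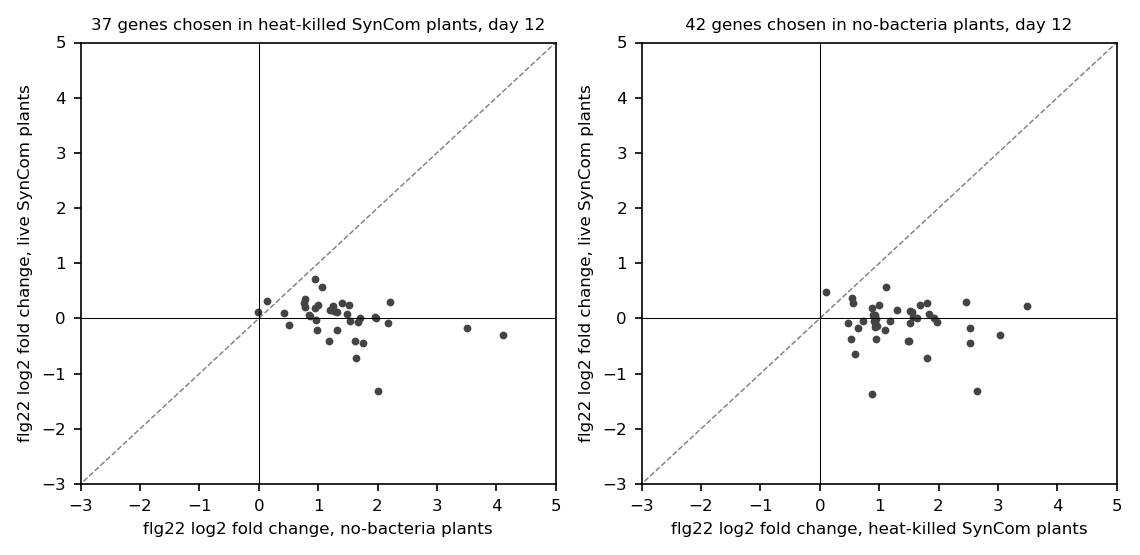
Each point is a gene raised at least 2-fold by flg22 in heat-killed SynCom plants (left, 37 genes) or in plants without bacteria (right, 42 genes), with the log2 fold change of flg22 against mock at day 12 in the remaining non-live group on the horizontal axis and in live SynCom plants on the vertical axis. The dashed line marks equal effects, and 35 of the 37 and 41 of the 42 points lie below it.

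Live SynCom by itself had a larger count at day 12 (9 against 7 mock libraries). AT1G34510 rose from 2.32 ± 2.44 CPM (SD, n = 7) to 60.6 ± 48.6 CPM (SD, n = 9), a log2 fold change of 4.54 ± 0.51 (edgeR adjusted p = 5.82e-10), PRP1 rose by 3.97 ± 0.44 and AT1G33840 by 3.38 ± 0.25 (edgeR adjusted p = 2.98e-16). AT1G28040 (3.69), the amino acid transporter-like gene UMAMIT35 (2.96), the pectin lyase-like gene AT1G11920 (2.93), AT1G45015 (2.72) and AT1G50050 (2.28) were also higher. The auxin glucosyltransferase gene UGT74E2 (AT1G05680, 1703002 to 1704838) went from 218 ± 74.2 CPM (SD, n = 7) to 10.5 ± 9.90 CPM (SD, n = 9) and fell by 4.62 (SE 0.36, edgeR adjusted p = 1.74e-14). BGLU11 went from 362 ± 109 to 28.7 ± 8.20 CPM and fell by 3.72 (SE 0.16, edgeR adjusted p = 2.04e-25), GSTU24 fell by 3.39 (SE 0.18) and GSTU25 by 2.83, with AT1G26390 (-4.14), AT1G60750 (-3.34), AT1G58320 (-3.33) and AT1G60730 (-3.14) lower too.

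Gene groups moved in both directions with live SynCom at day 12. Of 12 mannose-binding lectin and jacalin genes 6 were higher, led by AT1G60110 (2.15 ± 0.24), AT1G33790 (1.19 ± 0.14), AT1G52060 (1.24) and AT1G52070 (1.06), with camera adjusted p = 0.0027, and adjusted p = 0.00921 with an estimated correlation. Of 15 NAC transcription factor genes 6 were lower, led by NAC001 (-1.23), ATAF1 (-1.53), NAC003 (-1.49) and NAC010 (-1.0), with camera adjusted p = 0.000415, and adjusted p = 0.00921 with an estimated correlation. Of 7 berberine bridge enzyme genes 4 were lower, AT1G26390, AT1G26380 (-2.29), AT1G30700 (-1.04) and AT1G26420 (-1.93), with camera adjusted p = 0.00129, and adjusted p = 0.211 with an estimated correlation. Without the no-bacteria mock libraries of experiment 3, AT1G26420 was not called (-1.09, edgeR adjusted p = 0.0568) and AT1G26380 was called at a smaller change of -1.31 (edgeR adjusted p = 0.0209). Ribosomal protein genes included 12 higher and 1 lower of 41 (camera adjusted p = 0.00132), and adjusted p = 0.481 with an estimated correlation.

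Among smaller lists, both jasmonate genes tested were higher, the transcription factor gene MYC2 (0.73 ± 0.09) and its repressor JAZ1 (0.83 ± 0.14). Of 5 nitrate genes 3 were lower, NIA2, which encodes nitrate reductase (-1.06 ± 0.12), NRT2.2 (-1.18) and NRT2:1 (-0.65), over all genes and adjusted over the list alone alike (camera adjusted p = 0.117). Both phenylpropanoid genes tested, 4CL1 (-0.49) and CCR1 (-0.22), 2 of 3 Casparian strip and suberin genes, KCS2 (-0.66) and LACS2 (-0.51), and FMO1 (-2.52 ± 0.36) were lower. Of 5 indole glucosinolate genes UGT74B1 rose by 0.56, and IGMT1 (-1.11) and IGMT2 (-1.13) were lower. For each of these lists the number of calls adjusted over the list alone was the same. SD1-29 rose by 0.52, PHI-1 by 0.87 and the replication gene MCM2 by 0.26, while AT1G14130 fell by 1.18. Without the no-bacteria mock libraries of experiment 3, IGMT1 (-0.32, edgeR adjusted p = 0.627), IGMT2 (-0.16, edgeR adjusted p = 0.83), PHI-1 (0.56), SD1-29 (0.39) and MCM2 (0.17) were not called. In total 282 genes were higher and 344 lower of 3320, 46 and 64 at least 2-fold, and 616, 601 and 617 of the 626 had the same sign in experiments 1, 2 and 3, within which 315, 203 and 674 were called. The count was 463 without the no-bacteria mock libraries of experiment 3, 585 without the library highest in photosynthesis transcripts, 410 with no experiment term and 381 with counts summed per experiment.

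**Figure D3:**
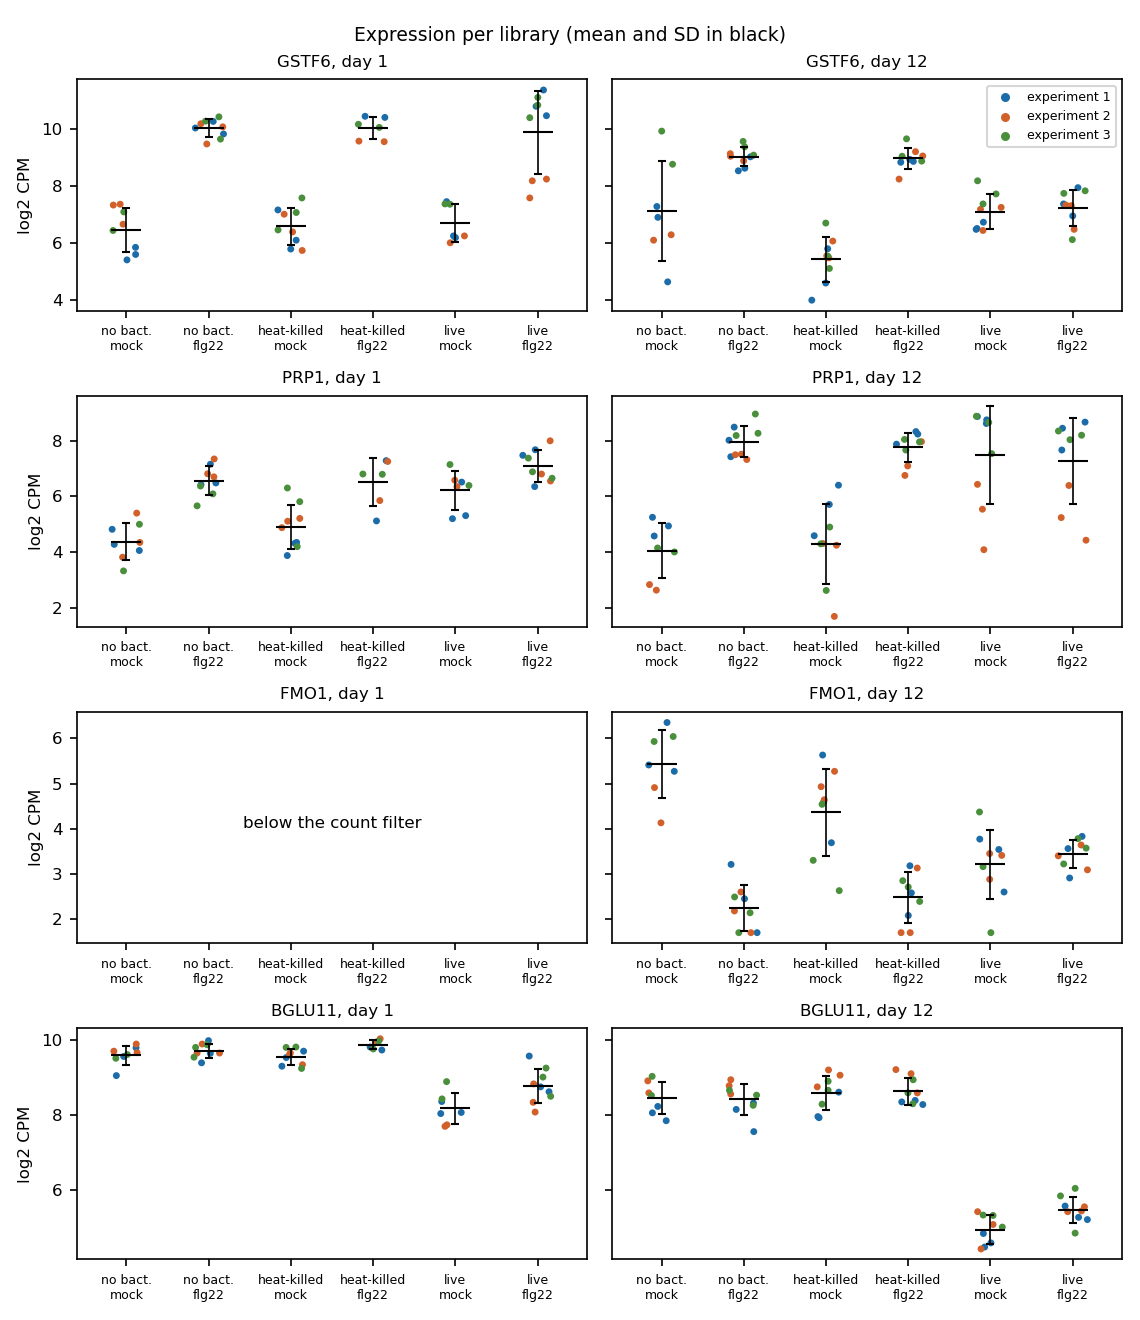
Points are single libraries coloured by experiment, with log2 CPM over the genes held on the vertical axis and group mean and SD in black, for GSTF6, PRP1, FMO1 and BGLU11 at day 1 (left) and day 12 (right). FMO1 did not pass the count filter at day 1, and at day 12 it stood at 45.0 CPM in mock and 1.76 CPM with flg22 without bacteria.

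Live against heat-killed SynCom at day 12 (9 and 9 mock libraries) gave 261 higher and 336 lower genes, 44 and 54 at least 2-fold. AT1G34510 was higher by 3.88, AT1G33840 by 3.29, PRP1 by 3.12 and AT1G28040 by 3.09. UGT74E2 was lower by 4.43, BGLU11 by 3.82 (SE 0.16, edgeR adjusted p = 1.3e-26), GSTU24 by 3.41 and AT1G60730 by 3.15. Of 12 mannose-binding lectin and jacalin genes 5 were higher (camera adjusted p = 0.000372), and adjusted p = 0.00137 with an estimated correlation, and of 15 NAC genes 5 were lower and 1 higher (camera adjusted p = 0.000742), and adjusted p = 0.0112 with an estimated correlation. The iron reductase gene FRO2 was lower by 0.78. Of the 597 calls, 577, 578 and 585 had the same sign in experiments 1, 2 and 3, within which 400, 492 and 243 genes were called, and the count was 390 with no experiment term and 352 with counts summed per experiment.

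Heat-killed SynCom at day 12 (9 against 7 mock libraries) lowered 3 of 3320 genes, GSTF6 (-2.27, SE 0.41, edgeR adjusted p = 0.00433), GSTF7 (-1.82, SE 0.35, edgeR adjusted p = 0.00522) and AT1G26380 (-1.78, SE 0.34, edgeR adjusted p = 0.00522), the last named after its values were seen because its sign differed in experiment 2. DESeq2 called 3 genes, and 128 had an unadjusted p under 0.05, a share that is itself below 0.05. The mock group without bacteria held a wide spread in these genes, with GSTF6 at 259 ± 335 CPM and GSTF7 at 453 ± 581 CPM (SD, n = 7). GSTF6 stood at 427 and 956 CPM in the 2 libraries of experiment 3 and between 21.5 and 152 CPM in the others. Without those 2 libraries 0 genes were called, and GSTF6 had a difference of -1.02 (edgeR adjusted p = 0.885). Within experiments 1, 2 and 3 the counts were 32, 0 and 432, and the pooled count was 2, 15 and 0 without each in turn, 0 in a fit of only these groups and 0 with counts summed per experiment. The cell cycle and indole glucosinolate lists held 0 called genes and each gave camera adjusted p = 0.0409, and adjusted p = 0.426 with an estimated correlation.

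Overlap between the effects of flg22 and of live SynCom was examined against the shared mock libraries without bacteria. At day 12, 42 genes were higher in both, PRP1 and AT1G34510 among them, 19 were lower in both, FMO1 among them, and 13 moved in opposite directions. Independent lists of these sizes would share 9.43 and 4.66 genes, and with the controls split the counts averaged 23.2 and 10.3. Each split effect was measured against only a part of the control libraries, which can shorten the lists of calls. The sizes of those lists are not given here, so the lower counts cannot be put down to shared controls alone. Simulated unchanged groups shared 0 and 0, but groups without effects give few calls to share, so that count says little about the overlap. Across the 3320 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.349, against 0.514 for simulated unchanged groups and 0.244 (0.097 to 0.291) with split controls. The covariance was 0.049 against a simulated 0.012. At day 1 the overlap was 3 genes higher and 1 lower in both and 6 opposite, where independent lists would share 0.812 and 0.922 and split controls gave averages of 1.1 and 0. The r was -0.001, against 0.517 for simulated unchanged groups and -0.147 (-0.291 to 0.036) with split controls.

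Time was compared in mock plants without bacteria (7 libraries at day 12, 8 at day 1). Of 3366 genes 903 were higher at day 12 and 889 lower, 241 and 155 at least 2-fold. The pectin lyase-like gene AT1G10640 was higher by 6.82 ± 0.43 (edgeR adjusted p = 1.97e-25), the mannose-binding lectin gene AT1G52120 by 5.75, BGLU1 by 5.73 and FMO1 by 5.23 ± 0.57. BCAT-2, which encodes a branched-chain amino acid transaminase, was lower by 6.13 (SE 0.40, edgeR adjusted p = 3.13e-23), the threonine aldolase gene THA1 by 5.69, AT1G21400 by 5.69 and the defensin-like gene PDF1.4 by 5.55. All 5 nitrate genes tested were higher, NRT2:1 (2.77), NRT2.2 (2.77), NRT1.1 (1.84), NIA2 (1.04) and HRS1 (0.93), over all genes and adjusted over the list alone alike (camera adjusted p = 0.000176), and adjusted p = 0.0244 with an estimated correlation. Of 4 auxin genes 3 were higher, SHY2 (2.18), PIN7 (1.04) and ARF19 (0.51), and 4 passed when adjusted over the list alone (camera adjusted p = 0.036), and adjusted p = 0.0843 with an estimated correlation. Of 6 iron genes 3 were higher, FRO2 (2.08) and MYB72 (2.07) among them, and 2 were lower, AT1G47395 (-2.75) and AT1G47400 (-1.88), which encode iron-deficiency peptides, with 5 passing when adjusted over the list alone (camera adjusted p = 0.948). Without the no-bacteria mock libraries of experiment 3 at day 12, 1717 genes were called. Plants of the 2 days also differ in age and in harvest, which the design does not separate.

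The flg22 effect without bacteria differed between days for 41 of 3366 genes, 29 higher and 12 lower at day 12, 15 and 7 by at least 2-fold. The effect on AT1G09750 was higher by 3.35 ± 0.46 (edgeR adjusted p = 2.19e-07), on the acyltransferase-like gene AT1G34520 by 2.48, on AT1G52190 by 1.75 and on AT1G54890 by 1.67. It was lower on AT1G26390 by 2.63, on GSTF7 by 2.58 (SE 0.48), on GSTF6 by 2.19 (SE 0.50, edgeR adjusted p = 0.0129) and on AT1G26250 by 1.46. Without the no-bacteria mock libraries of experiment 3, 10 genes were called. AT1G34520 (2.43) and AT1G52190 (1.71) were not among them though their differences hardly moved, nor were AT1G26390 (-1.95) and AT1G26250 (-1.30), and the difference was -1.54 for GSTF7 (edgeR adjusted p = 0.134) and -0.99 for GSTF6 (edgeR adjusted p = 0.523). RLE scaling called 19 higher and 11 lower, and the count was 25 with no low-count filter, 10 without experiment 1, 10 without experiment 3, 9 with no experiment term, 9 with additive experiment terms and 2 with counts summed per experiment.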

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

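The tests of the no-bacteria mock libraries, of single experiments, of genes already raised by live SynCom and of exchanged labels were chosen after the results they bear on were seen, while the test of shoot tissue was set before its result was seen.

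The flg22 effect at day 12 differed between live SynCom and no bacteria for 98 genes and between live and heat-killed SynCom for 134, with median differences of -1.18 and -1.31 over genes that flg22 raised in the remaining kind of plants. Without the no-bacteria mock libraries of experiment 3 the median, live minus none, was -1.43 (quartiles -1.90 and -1.04, 0 of 37 genes above 0). The difference thus remained without those libraries. GSTF6, which was high in them, had a flg22 effect without bacteria of 1.25 with them and 2.5 without. For such genes leaving them out could only enlarge the difference, so that median cannot decide whether they are a source. The within-experiment medians, live minus heat-killed, were -1.09, -0.92 and -1.63, which argues against a single experiment as the source of the difference. The median live SynCom effect in mock plants was 0.32 over the 37 genes (quartiles -0.25 and 1.35), against a median flg22 effect of 1.27, which left open how far genes already raised by live SynCom account for it, with 13 of 37 raised at least 0.5 times as much. A further comparison, chosen because that one was undecided, set live SynCom plants with flg22 against plants with flg22 and no bacteria. Its median was -0.96 with an upper quartile of -0.40. Most of the 37 genes thus stayed below the level that flg22 gave without bacteria. For each gene this value follows from the live SynCom and flg22 effects already seen. It is therefore no separate test of the cause, which stays open. For single genes the level already raised by live SynCom in mock plants remains a candidate. PRP1 had a live SynCom effect of 3.97 in mock plants against a flg22 effect of 4.11 without bacteria. For AT1G34510 these were 4.54 and 3.5. With all libraries, 22 of the 37 genes had a live SynCom effect above 0 in mock plants, so there this does not cover them all. The medians of 0.32 and 1.27 and the counts of 13 and 22 were not run without the no-bacteria mock libraries of experiment 3. Without them the live SynCom effect went from -1.52 to -0.40 for GSTF7 and from -1.13 to -0.16 for IGMT2. It went from 4.54 to 4.25 for AT1G34510 and from 2.15 to 2.05 for AT1G60110. How many genes are covered thus remains open. A lower response of the root to flg22 or a loss of the peptide from the medium with live bacteria may each explain a part of the difference. Both are hypotheses that were not tested.

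At day 12 both no-bacteria mock libraries of experiment 3 had high levels of GSTF6, at 427 and 956 CPM against 21.5 to 152 CPM in the other 5. If mock and flg22 labels had been exchanged, the flg22 effect within experiment 3 would lie at or below 0 over the 37 genes that flg22 raised with heat-killed SynCom, but its median was 1.25 with a lower quartile of 0.50. FMO1 stood at 57.9 and 62.6 CPM in these libraries, and at 1.76 ± 1.92 CPM (SD, n = 9) with flg22. What else could set these libraries apart was not tested, and the design gives no biological group that separates them.

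The summed photosynthesis level had a log2 value of 12.78 in live mock replicate 3 of experiment 2 at day 12, against a group median of 10.57, and 2 live SynCom libraries of experiment 2 at day 1 were also high. Over 11 genes annotated to photosynthesis outside the list fixed before, the median log2 ratio to the rest of the group was 1.81, 1.98 and 1.34 in the 3 libraries, so that shoot tissue in the root sample is a candidate source. CAB2, a chlorophyll-binding protein gene, averaged 386 ± 819 CPM (SD, n = 7) in the live mock group at day 1. All 6 markers also passed the count filter in these roots, and no biological explanation was tested.

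The flg22 effect without bacteria differed between day 12 and day 1 for 41 genes. The remaining results concern single libraries far from the rest of their group, of which 7 were found in 108 groups tested, where chance gives about 1 in 20. The total count was 630981 in live flg22 replicate 1 of experiment 2 at day 1 (group median 420538) and 777629 in no-bacteria flg22 replicate 1 of experiment 3 at day 1 (group median 445530). BGLU11 had a log2 CPM of 9.05 in no-bacteria mock replicate 2 of experiment 1 at day 1 (group median 9.64). GSTU24 had 9.98 in live flg22 replicate 1 of experiment 1 at day 1 (9.10) and 8.07 in live flg22 replicate 2 of experiment 3 at day 12 (6.47). AT1G34510 had 2.58 in heat-killed flg22 replicate 2 of experiment 2 at day 12 (4.53).

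Other splits of the libraries, 100 for each comparison with the real one included, were fitted on only the groups compared. The splits moved single libraries without regard to experiment, so they do not test whether a difference recurs over the 3 experiments. A random division of libraries is an unlikely source where 1 split, the real one, gave as many calls. At day 1 this held for flg22 without bacteria (69 genes, highest other split 1) and live against heat-killed SynCom (125, highest other 1). At day 12 it held for flg22 without bacteria (159, highest other 49), with live SynCom (15, highest other 3) and with heat-killed SynCom (210, highest other 5), for live SynCom in mock (578, highest other 255), live against heat-killed SynCom (446, highest other 223), the flg22 effect with live SynCom against no bacteria (96, highest other 3) and against heat-killed SynCom (113, highest other 9), day 12 against day 1 (1505, highest other 0) and the flg22 effect between days (31, highest other 1). At day 1, 2 of 100 splits gave as many as flg22 with live SynCom (31, highest other 292), 3 as many as flg22 with heat-killed SynCom (78, highest other 155) and 2 as many as live SynCom in mock (149, highest other 194). Each share is under 0.05, but another split called more genes than the real one, so that a random division is set aside less firmly for these 3. For flg22 with live SynCom at day 12 the planned fit called 1 gene, and 258, 0 and 7 were called within experiments 1, 2 and 3. The splits leave that comparison unsettled. A comparison with 0 calls cannot have a split with fewer, so that all 100 splits gave as many and the count says nothing about chance: heat-killed SynCom in mock at day 1 (highest other 140) and day 12 (1), the day 1 differences of the flg22 effect for live against none (122), heat-killed against none (1) and live against heat-killed (0), and heat-killed against none at day 12 (2). Other splits with 292, 155, 194, 140 and 122 calls at day 1 point to a structure of the samples, and what it follows was not tested.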

How the results depend on the processing

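The settings that leave out the no-bacteria mock libraries of experiment 3 or the libraries highest in photosynthesis transcripts were chosen after seeing the data, and all other settings were set before. RLE scaling kept all 26 results it was run on within 1.5 times the planned count or on the same side of the test, DESeq2 18 of 20, no low-count filter 19 of 20, the replicate block 25 of 26 and no fold floor 5 of 5. The numbers kept were 17 of 26 with no experiment term, 6 of 20 with counts summed per experiment, 17 of 20 in a fit of only the groups compared, and 15 of 23, 16 of 25 and 17 of 25 without experiments 1, 2 and 3. Of 171 results for named genes, 0 reversed. The naming rule took only called genes with the same sign in each experiment, so a reversal was unlikely by construction. Calls were lost for 1 of these results with DESeq2, 2 with RLE scaling, 4 with no filter and 8 with the block. With no experiment term 19 calls were lost, and with counts summed per experiment 57. Calls were lost for 43 of 165 without experiment 1, 22 of 167 without experiment 2, 32 of 171 without experiment 3, 12 of 131 with only the groups compared, 3 of 16 with additive experiment terms, 16 of 66 without the no-bacteria mock libraries of experiment 3 and 4 of 86 without the libraries highest in photosynthesis transcripts. Unless the construction shows the cause, as with fewer samples, the cause was not tested. Small changes can be missed: in simulated data for the flg22 effect without bacteria at day 1, 46% of genes changed by 0.5 on the log2 scale were called. How depth and sample number bear on this was not tested.

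With counts summed per experiment, which leaves 3 sums per group, the day 1 counts became 25 for flg22 without bacteria (71 in the planned fit), 34 with live SynCom (57), 33 with heat-killed SynCom (68), 84 for live SynCom in mock (155) and 75 for live against heat-killed SynCom (137). At day 12 they became 62 for flg22 without bacteria (156), 0 with live SynCom (1), 74 with heat-killed SynCom (228), 381 for live SynCom in mock (626), 0 for heat-killed SynCom in mock (3), 352 for live against heat-killed SynCom (597), 11 for the flg22 effect of live against none (98), 20 for live against heat-killed (134) and 2 for flg22 between days (41). No experiment term gave, in the same order at day 12, 71 for flg22 without bacteria, 0 with live and 114 with heat-killed SynCom, 410 for live SynCom, 390 for live against heat-killed SynCom, 30 and 42 for the live differences and 9 for flg22 between days.

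Each experiment was left out in turn. At day 1 the counts ranged from 30 to 60 for flg22 without bacteria, 17 to 230 with live SynCom, 21 to 33 with heat-killed SynCom, 33 to 220 for live SynCom in mock, 55 to 139 for live against heat-killed SynCom and 0 to 1 for the flg22 difference of live against heat-killed. At day 12 they ranged from 0 to 52 for flg22 with live SynCom, 145 to 203 with heat-killed SynCom, 0 to 15 for heat-killed SynCom in mock, 46 to 107 for live against none, 0 to 6 for heat-killed against none, 44 to 209 for live against heat-killed and 10 to 57 for flg22 between days.

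The fit of only the groups compared gave 31 for flg22 with live SynCom at day 1, 15 at day 12 and 0 for heat-killed SynCom in mock at day 12. DESeq2 gave 12 for flg22 with live SynCom at day 12, with 1159 adjusted p-values not assigned, and 1 for heat-killed against none. For flg22 between days, no low-count filter gave 25, additive experiment terms 9 and omission of the no-bacteria mock libraries of experiment 3 gave 10. That omission also gave 61 for live against none and 0 for heat-killed SynCom in mock. Without the libraries highest in photosynthesis transcripts the counts were 100 for live SynCom in mock at day 1, 1 for live against heat-killed at day 1 and 2 for flg22 with live SynCom at day 12. The median difference of heat-killed minus none at day 1 changed sign from -0.03 to 0.01 with no experiment term and was 0.053, 0.002 and -0.005 without experiments 1, 2 and 3. In the same order live minus heat-killed (0.14) was -0.08, 0.37 and 0.03, and live minus none (0.21) was 0.07, 0.32 and 0.14, some of them over fewer than 10 genes and then without a test. Of 191 gene list tests 17 were called at the preset correlation, 3 with an estimated correlation, and 14 to 25 with an experiment left out.

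Replicate numbers gave little sign of pairing the libraries. Libraries with the same number in an experiment had a mean correlation of 0.0027 at day 1 and 0.0056 at day 12. With other numbers it was -0.0013 and -0.0029. Of 48 and 52 libraries, 20 and 22 were closest to their own number, and no chance rate was set beside these counts. As a block, the replicate number gave 18 calls for flg22 between days, and 63, 51 and 51 calls at day 1 for flg22 without bacteria, with live and with heat-killed SynCom, and it moved no other count by over 1.5 times.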

Other observations

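Protein families and annotated processes were chosen after the range of genes was seen and before any test was run on them. Of 21 genes annotated to the response to oxidative stress, flg22 at day 12 raised 8 without bacteria (camera adjusted p = 1.42e-07, and adjusted p = 0.056 with an estimated correlation) and 6 with heat-killed SynCom (camera adjusted p = 3.23e-07, and adjusted p = 0.0353 with an estimated correlation). The effect on this group was lower with live than with heat-killed SynCom for 5 of the 21 (camera adjusted p = 0.000201, and adjusted p = 0.482 with an estimated correlation). The amino acid transporter-like family nodulin MtN21 held 1 of 8 genes with a lower flg22 effect in live than in heat-killed SynCom plants, UMAMIT28 (-0.54 ± 0.12, edgeR adjusted p = 0.00311), and 4 when adjusted over the list alone (camera adjusted p = 0.00182, and adjusted p = 0.0075 with an estimated correlation). Of 12 glutathione S-transferase genes, live SynCom in mock plants at day 12 raised 2, GSTF14 (1.33 ± 0.17) and GSTU26 (0.52 ± 0.15), and lowered 4, GSTU24 (-3.39), GSTU25 (-2.83), GSTU16 (-1.96) and GSTF7 (-1.52), and the family as a whole did not pass (camera adjusted p = 0.0608). GSTF7 stood at 899 and 1597 CPM in the no-bacteria mock libraries of experiment 3 and at 66.0 to 213 CPM in the other 5. Without those libraries, a setting chosen after the data were seen, GSTF7 (-0.40 ± 0.32, edgeR adjusted p = 0.492) and GSTU26 (0.42 ± 0.16, edgeR adjusted p = 0.0708) were not called.

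Between day 1 and day 12 in mock plants without bacteria, 5 of 6 cell cycle and replication genes were higher, among them the cyclin gene CYCA1;1 (0.91 ± 0.18), the kinesin gene HIK (0.83 ± 0.15) and PCNA1 (0.54 ± 0.13), and 5 when adjusted over the list alone, while the list as a whole did not pass (camera adjusted p = 0.229). Of 42 ribosomal protein genes 20 were lower and 3 higher (camera adjusted p = 0.0195, and adjusted p = 0.679 with an estimated correlation). The lignin pathway gene 4CL1 was higher (2.15 ± 0.14) and the indole glucosinolate methyltransferase gene IGMT1 lower (-2.61 ± 0.27). Age and harvest are not separated from time in these values.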
